A study of Mus musculus with 6 samples.

How the data were processed

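The samples were total RNA from primary hepatocytes of wild type mice and of mice with a hepatocyte-specific SRSF1 knockout, 3 of each, hybridised to 1 mouse exon array each. Per the labels' protocols, hepatocytes were harvested by perfusion at 3 months of age, RNA was isolated with a column kit and RNA quality was checked on a Bioanalyzer. Groups were taken from the genotype in the labels, and replicate numbers name the arrays only. The labels also call the cells primary hepatocyte cultures; a time in culture is not given in the sources used here.

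The deposited values are array intensity summaries made with PLIER, per the submitters' processing notes, which also name the mm9 genome build. The labels call them PLIER-normalized values of the full set of exons. The PLIER version, the background step and the normalization between arrays are not given in the sources used here. From the values, the intensities are on a linear scale, all positive, and reach 19074. Their medians run from 18.6 to 39.8 between arrays, so the columns do not share a distribution, and which part of that comes from the samples is unknown. No columns were left unused and no replicates were pooled.

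The table held 238609 rows, of which the platform annotation listed 26140. Of these, 24343 carry 1 gene symbol and 1797 several; the other 212469 are unnamed here. Rows with several symbols were named as no gene. Abundant liver genes have 1 bright row each, so a row is a transcript cluster and not an exon. The planned test of exon usage (limma's diffSplice) needs several rows per gene and was not run; splicing, the process SRSF1 acts in, is not analysed here. A gene value adds up signal over a whole transcript unit and can move with the exons used as well as with the amount of RNA. No coordinates are printed, because the reference annotation at hand (GRCm38.p6, used for names of genes only) is of another build than the array annotation.

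Values were transformed as log2(intensity + 16), and differences of dim genes are understated on that scale. Clusters under the 40th percentile of mean log2 value (5.18) were left out, which kept 143165. For each gene the cluster of the highest mean was used, which gave 19123 of 20261 genes. These values were compared between knockout and wild type with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, no covariates, no further normalization), with Benjamini-Hochberg adjustment and a threshold of 0.05. On the deposited values the fit found no gene-to-gene spread of variances beyond chance and pooled them fully at each intensity, which makes its p-values very small where arrays differ in scale as a whole. The same model was run after quantile normalization of all rows between arrays, one of the alternatives fixed beforehand. The rule that a change needs both fits was set after the data had been examined. Leading values were also computed without knockout replicate 1, chosen after seeing its X-linked and Y-linked signal.

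The fits were tested on simulated data with 19123 genes, of which 200 were changed by known amounts. With no offset between arrays the test on the deposited scale called 7 unchanged genes and recovered 70% of 1 log2 unit decreases and 57.5% of 1 log2 unit increases. With the measured array offsets it called 251 unchanged genes, 247 of them lower, and recovered 0% of increases of 1 log2 unit. Quantile normalization brought this to 6 unchanged genes called, with 70% of increases and 55% of decreases of that size recovered, and 92.5% and 97.5% of increases and decreases of 2 log2 units. The simulated offset was 1 constant per array, which quantile normalization removes by construction, and genes were drawn independently. The real arrays also differed in spread (interquartile range of log2 values 1.55 to 2.14). These counts therefore do not give the number of false calls in the real data.

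Gene lists (41, of 996 members with 810 measured) were fixed before the data were examined. Of these, 39 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry; the sex chromosome list served to check the animals and the list of reported SRSF1 targets was meant for exon usage and was not used. Camera compares a list with other genes, so a list can be called up while its own median is below 0. A list adjusted over the list alone uses the p-values of its own members.

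The genes named were fixed by rule beforehand: Srsf1; the 12 largest increases and 12 largest decreases on the deposited values among genes past the threshold whose groups did not overlap (162 and 1158 were eligible), leaving out gene models and olfactory and vomeronasal receptors; and up to 4 members per list by p-value, or 6 where most of the list passed. Further called members of a list were named after their values were seen, to complete its count. Alternatives tried were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median centring, no trend, robust variances, the median of a gene's clusters, array weights, a log2 difference of at least 1, and leaving out each array in turn. Arrays of the groups share no replicate numbers in the labels, so no pairing was tested.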

Results

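Gene expression was measured on mouse exon arrays in primary hepatocytes taken by liver perfusion from C57BL/6 mice aged 3 months. The knockout mice lacked SRSF1, an SR protein that binds pre-mRNA and takes part in splice site choice, in hepatocytes only. The series held 3 wild type and 3 knockout samples with 1 array each, and none was treated. The sample titles carry a running number and a further number that differs between samples, but the labels do not say whether the latter marks an animal, so p-values measure the spread between these samples, which may be technical. This further number of knockout replicate 1 lies among those of the wild type samples, and those of the other knockout samples are higher; what this order stands for is not given. Each of the 238609 rows was a transcript cluster, meaning a summary over the probes of 1 transcript unit, and 19123 genes with 1 symbol each were tested. The small number of arrays limits the precision of every value.

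The arrays were not on a common scale. The median deposited intensity over all transcript clusters was 31.8, 39.8 and 25.6 in wild type replicates 1, 2 and 3, and 28.8, 18.6 and 20.8 in knockout replicates 1, 2 and 3. The median gene therefore lay -0.44 log2 units lower in the knockout than in wild type on the deposited values, and -0.01 after quantile normalization. Log2 differences below are knockout minus wild type after quantile normalization, given with their standard error (3 against 3 arrays), and intensities are means ± SD of the deposited values. A gene is said to have risen or fallen only where it passed a Benjamini-Hochberg adjusted p of 0.05 in limma's test both on the deposited values and after quantile normalization, in the same direction. Camera's adjusted p-values for single lists, at either correlation, are from the deposited values unless stated otherwise.

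Knockout replicate 1 stood apart from the other 5 arrays. Xist, the noncoding RNA transcribed from the inactive X chromosome, had an intensity of 9.95 in it and of 2122 to 3532 in the others. The Y-linked gene Eif2s3y had 130 in it and 2.27 to 7.78 in the others, and the Y-linked gene Kdm5d 132 against 12.1 to 35.8. By these genes, knockout replicate 1 came from a male and the other arrays from females. Across genes, its log2 values correlated at 0.939 and 0.945 (Pearson's r) with those of the other knockout arrays, which correlated at 0.987 with each other. Knockout replicates 2 and 3 correlated more closely with the wild type arrays (0.952 to 0.966) than with knockout replicate 1. The log2 values of knockout replicate 1 also had the narrowest interquartile range, 1.55 against 1.85 to 2.14 in the others. Which part of these differences goes with sex was not tested. The main counts and the differences of leading genes are therefore also given without knockout replicate 1.

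**Figure D1:**
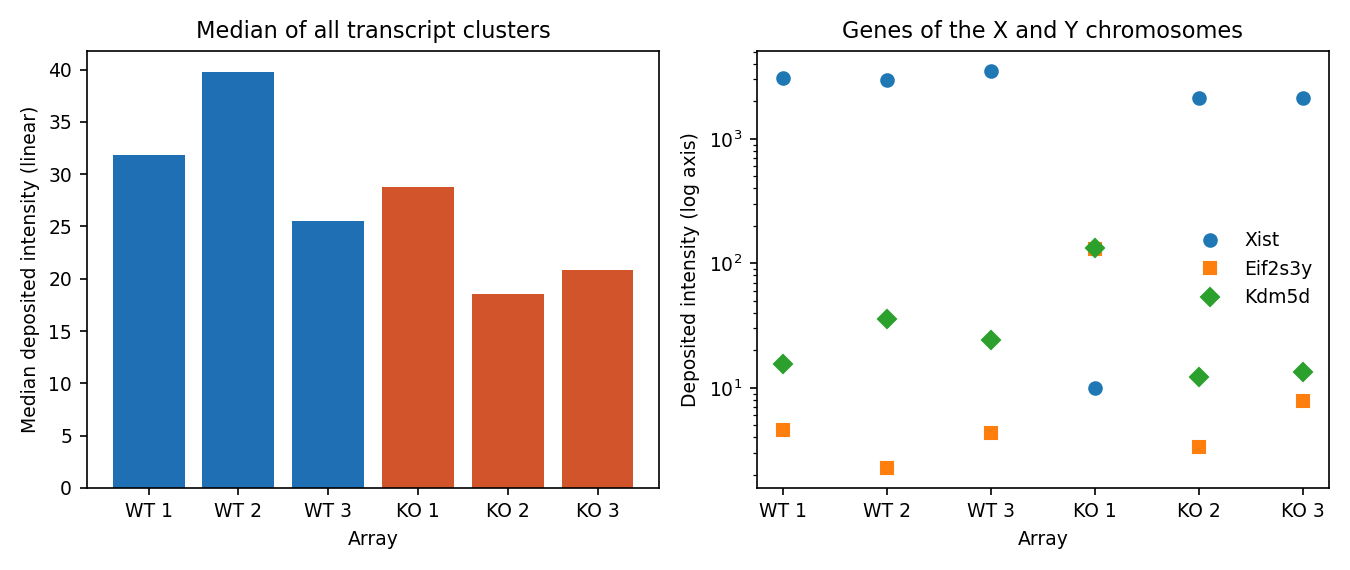
Median deposited intensity of all transcript clusters per array (left, linear axis from 0) and deposited intensity of Xist, Eif2s3y and Kdm5d per array (right, log axis). WT marks wild type and KO knockout arrays, numbered by replicate. Medians run from 18.6 to 39.8, and KO 1 has the lowest Xist (9.95) and the highest Y-linked signal (130 and 132, overlapping points).

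The targeted gene itself had a lower signal in the 3 knockout arrays than in the 3 wild type arrays. The Srsf1 transcript cluster (6783359) read 666, 667 and 607 in wild type and 242, 371 and 386 in the knockout, a knockout mean of 51.5% of the wild type mean. On the deposited values its log2 difference was -0.95 ± 0.27 (adjusted p = 0.010). After quantile normalization it was -0.53 ± 0.18 (adjusted p = 0.185), and without knockout replicate 1 it was -0.35 ± 0.12. An exact two-sided permutation test of this 1 gene gave p = 0.1, the smallest that 3 against 3 arrays allow. The cluster joins probes along the whole transcript and the labels do not give the deleted exons, so probes outside the deleted part are included and the value is a weak check of the labels. A dimmer Srsf1 cluster (6790588) read 18.1, 37.1 and 22.0 in wild type and 21.4, 18.1 and 12.8 in the knockout.

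The comparison of knockout with wild type asks which transcripts differ in hepatocytes labelled as lacking this splicing factor. Among the fixed lists, 6 of 17 fetal liver markers and 11 of 34 cell cycle genes rose in the knockout. So did 6 of 22 genes of the actin cytoskeleton and dedifferentiation in culture, called cytoskeletal genes below. In the lists of bile acid, fatty acid oxidation and glucose genes 6 of 22, 4 of 24 and 6 of 22 fell, and the bile acid list also held 1 gene that rose. The shifts of these 6 lists as wholes were not called with an estimated correlation (adjusted p = 0.146, 0.146, 0.264, 0.681, 0.502 and 0.681). H19, an imprinted noncoding RNA abundant in fetal liver, had the largest increase: its intensity was 40.5 ± 31.8 in wild type and 1474 ± 618 in the knockout, a log2 difference of 5.20 ± 0.38 (adjusted p = 0.00022). In wild type replicates 2 and 3 it read 20.7 and 23.6, below the medians of those arrays, so the size of the difference depends on the scale used. Sult3a2 and Sult3a1, a pair of closely related sulfotransferases, had the largest decreases with all arrays and the main pseudocount. Sult3a1 went from 2397 ± 541 to 44.2 ± 33.4, a log2 difference of -5.03 ± 0.51 (adjusted p = 0.0012), and Sult3a2 from 1125 ± 340 to 8.38 ± 5.81, a difference of -5.16 ± 0.23 (adjusted p = 2.5e-05). Without knockout replicate 1 the differences were 5.20 ± 0.37 for H19, -4.40 ± 0.12 for Sult3a1 and -5.07 ± 0.18 for Sult3a2, and Rgs16 had a larger decrease (-5.27 ± 0.11). Sult3a2 read below the array median in all 3 knockout arrays and Sult3a1 in knockout replicate 1, so the sizes of their differences depend on the pseudocount; at 64 on the deposited values Rgs16 came before Sult3a2. Whether the probes tell these sulfotransferases apart was not tested here.

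In all, 428 genes passed in both fits, 161 higher and 267 lower in the knockout. On the deposited values alone 1489 genes passed, 178 higher and 1311 lower, so that 88.0% of the calls were lower. After quantile normalization alone 792 passed, 522 higher and 270 lower, so that 34.1% were lower. Because of the shift between the arrays, passing both fits asks for a larger increase than decrease, and the split of the 428 genes is not a balance of the direction of change. All 428 genes also passed in the same direction after quantile normalization without knockout replicate 1, a comparison among female arrays in which 2895 genes passed, 1863 higher and 1032 lower. The arrays of this comparison also served to choose the 428 genes, so their passing again is not an independent check. Without knockout replicate 1, all knockout samples also have higher title numbers than the wild type samples. The groups did not overlap for 29.7% of genes on the deposited values and 21.7% after quantile normalization, where chance gives 10%. The counts rested on single arrays: the count on the deposited values was 391, 496 and 7104 without wild type replicate 1, 2 or 3 and 3307, 743 and 623 without knockout replicate 1, 2 or 3. The count past both fits was 166, 194 and 240 without the wild type replicates in turn and 1198, 249 and 290 without the knockout replicates in turn. The excess of lower genes turned without wild type replicate 2 (102 higher, 92 lower) or wild type replicate 3 (150 higher, 90 lower). Without wild type replicate 1 it was nearly gone (82 higher, 84 lower). It held when any single knockout array was left out.

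Among the 12 genes with the largest increases, H19 was followed by Slpi, a secreted inhibitor of leukocyte proteases, at 4.54 ± 0.29, and by Cib3, of a family of calcium-binding proteins, at 4.54 ± 0.15. Cybb, the heavy chain of the phagocyte NADPH oxidase, rose from an intensity of 61.0 ± 18.8 to 699 ± 188 (3.67 ± 0.25). The complement component C6 rose by 3.56 ± 0.38, the imprinted gene Phlda2 by 3.32 ± 0.17 and Anxa2, a membrane-binding annexin, by 3.33 ± 0.29. Gpnmb, a glycoprotein abundant in some macrophages, rose by 3.03 ± 0.28 and the alpha tubulin Tuba8 by 3.10 ± 0.21. The others were Lrtm2 (3.81 ± 0.33), D17H6S56E-5 (3.62 ± 0.47) and Dhrs9 (3.46 ± 0.31). Their quantile-normalized adjusted p ran from 3.7e-06 for Cib3 to 0.0040 for D17H6S56E-5, and groups that do not overlap were a condition of the choice. Slpi, Cib3, Lrtm2 and Phlda2 read below the array median in all 3 wild type arrays, so the sizes and order of their differences depend on the pseudocount; at 64 on the deposited values Cib3 came before Slpi. Without knockout replicate 1 their differences ran from 3.08 for Anxa2 to 5.20 for H19. With the median of a gene's clusters in place of the brightest, the Tuba8 difference on the deposited values went from 2.66 to 1.07 and stayed past the threshold.

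Among the 12 largest decreases after the sulfotransferases, Rgs16, a regulator of G protein signalling, read 3842 ± 291 in wild type and 250 ± 337 in the knockout (-4.06 ± 0.74, adjusted p = 0.018). It read 639 in knockout replicate 1 and 61.1 and 50.3 in the other knockout arrays, its difference without replicate 1 was -5.27 ± 0.11, and its call on the deposited values was lost with robust variance estimates (adjusted p = 0.089). Pcp4l1 (-3.19 ± 0.33), the fatty acid elongase Elovl3 (-2.95 ± 0.20), the thioredoxin-binding protein Txnip (-2.46 ± 0.34), the sulfotransferase Sult5a1 (-2.17 ± 0.35), the lipogenic factor Thrsp (-2.0 ± 0.42) and the transcription factor Rfx4 (-2.0 ± 0.13) also fell. Without knockout replicate 1 the difference was -3.02 ± 0.10 for Txnip and -1.47 ± 0.20 for Thrsp, and with the median of its clusters that of Txnip on the deposited values went from -3.04 to -1.92. The remaining 3 passed on the deposited values only. Xist had a difference of -2.33 ± 1.45 (adjusted p = 0.547), and of -0.15 ± 0.14 without knockout replicate 1. Ces3b had -2.35 ± 0.67 (adjusted p = 0.100), and -1.44 ± 0.26 without that array, and Npr2 had -2.20 ± 0.52 (adjusted p = 0.0505), and -1.49 ± 0.12 without that array (adjusted p = 2.1e-05).

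**Figure D2:**
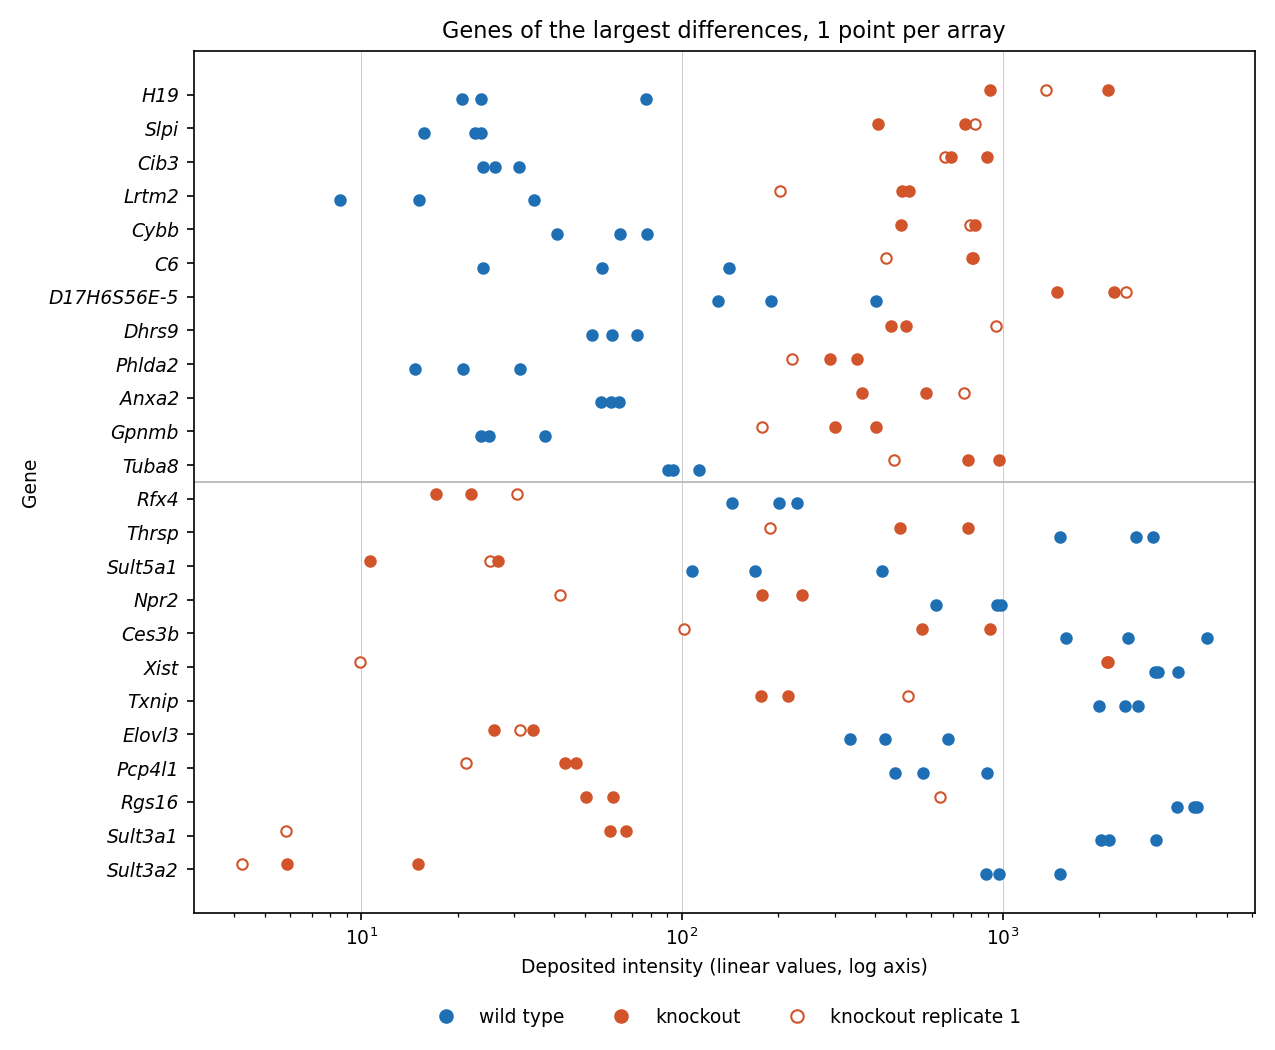
Deposited intensity (linear values on a log axis) of the 12 genes with the largest increases (above the line) and the 12 with the largest decreases (below the line) on the deposited values, 1 point per array. Blue points are wild type arrays, orange points knockout arrays and open points knockout replicate 1; H19 lies at 40.5 on average in wild type and at 1474 in the knockout, and the low mean of Xist rests on the open point at 9.95.

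Of 17 measured markers of fetal liver and liver cancer, 6 rose and none fell. Besides H19 these were Tff3, a secreted trefoil peptide (3.06 ± 0.20), the desaturase Scd2 (3.03 ± 0.28), Ly6d (2.97 ± 0.41), the fetal growth factor Igf2 (1.79 ± 0.38, at a low intensity of 7.52 in wild type and 54.7 in the knockout) and Igf2bp3, which binds Igf2 mRNA (1.64 ± 0.16). After quantile normalization 8 were higher and 1 lower when adjusted over the list alone. On the deposited values the list shifted up against other genes in camera's test with the preset correlation (adjusted p = 6.4e-32). The call was lost at adjusted p = 0.146 with an estimated correlation. After quantile normalization camera gave adjusted p = 1.6e-07 and 0.240 in these 2 forms.

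Of 34 cell cycle genes 11 rose and none fell. They included the mitotic cyclin Ccnb2 (2.39 ± 0.51), the spindle protein Prc1 (2.08 ± 0.41), the mitotic kinase Cdk1 (1.84 ± 0.29) and Plk1 (1.73 ± 0.39). The proliferation marker Mki67 had a difference of 2.0 ± 0.49 (adjusted p = 0.061) and was not called. The median over the list was 0.97, and 0.99 without knockout replicate 1. After quantile normalization, 25 were higher and 1 lower when adjusted over the list alone. In camera on the deposited values the list was up (adjusted p = 1.4e-37), lost at adjusted p = 0.146 with an estimated correlation. After quantile normalization camera gave adjusted p = 1.1e-14 with the preset and 0.240 with an estimated correlation. Macrophage markers (median 0.52) and stellate cell and matrix genes (median 0.35) were also higher after quantile normalization. The values therefore do not assign the cell cycle increases to hepatocytes.

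Of 22 genes of the list for the actin cytoskeleton and dedifferentiation in culture, 6 rose and none fell. The list holds tubulins, annexins and keratins among others. As a time in culture is not given, a difference in dedifferentiation between the groups was not tested. Anxa2 (3.33 ± 0.29), the beta tubulins Tubb6 (1.5 ± 0.19) and Tubb2a (1.49 ± 0.27) and the hepatocyte keratin Krt18 (1.32 ± 0.20) were among them, while Actb had a difference of -0.37 ± 0.33 (adjusted p = 0.725). After quantile normalization 15 were higher and 0 lower when adjusted over the list alone. The list was up in camera (adjusted p = 1.5e-20), lost at adjusted p = 0.264 with an estimated correlation. Its median after quantile normalization was 0.85, beside 0.52 for macrophage markers and 0.35 for stellate cell and matrix genes, and as several members are also expressed in such cells, the values do not assign the increases to hepatocytes.

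Stress and inflammation lists held few called genes. Among 15 NRF2 targets, genes of the oxidative stress response, Gstm3 (2.48 ± 0.17, from an intensity of 1085 to 4482) and Srxn1 (1.35 ± 0.21) rose. Of 21 p53 targets the death receptor Tnfrsf10b (1.63 ± 0.22) and the kinase Plk2 (1.39 ± 0.21) rose, while Cdkn1a had 1.51 ± 0.46 (adjusted p = 0.120). Of 23 interferon response genes the chemokine Cxcl10 (1.57 ± 0.18) and Oasl1 (1.39 ± 0.16) rose. Of 21 inflammatory and NF-kB genes the adhesion molecule Icam1 (1.51 ± 0.16) and Nfkb2 (1.31 ± 0.15) rose and the inhibitor Nfkbia fell (-0.73 ± 0.16). Adjusted over the list alone, 6 NRF2, 8 p53, 8 interferon and 7 inflammatory genes were higher and 0, 1, 1 and 2 lower after quantile normalization. Camera called these lists up (adjusted p = 5.3e-08, 1.2e-05, 1.2e-05 and 0.00047). With an estimated correlation the calls were lost, at adjusted p = 0.489, 0.502, 0.681 and 0.862. On the deposited values their medians were below 0 (-0.05, -0.10, -0.14 and -0.11), above the median gene at -0.44, and after quantile normalization they were above 0 (0.36, 0.38, 0.29 and 0.25).

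Of 22 measured genes of bile acid synthesis and transport, 6 fell, 1 rose and 15 did not pass. Cyp7b1 (-1.67 ± 0.36), Cyp8b1 (-1.10 ± 0.17) and Cyp27a1 (-0.94 ± 0.08), enzymes of bile acid synthesis, the sterol exporters Abcg8 (-1.23 ± 0.13) and Abcg5 (-0.82 ± 0.12) and the bile acid ligase Slc27a5 (-0.49 ± 0.11) fell, while the exporter Abcc4 rose by 2.68 ± 0.23. There were 9 lower and 3 higher genes after quantile normalization when adjusted over the list alone. The downward shift in camera (adjusted p = 0.00011) was lost at adjusted p = 0.681 with an estimated correlation.

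Of 24 genes of fatty acid oxidation and PPARalpha targets 4 fell and none rose. These were the thioesterase Acot3 (-1.53 ± 0.32), the pantetheinase Vnn1 (-1.22 ± 0.16), the isomerase Eci2 (-0.93 ± 0.17) and the fatty acid-binding protein Fabp1 (-0.39 ± 0.08), and the receptor Ppara itself fell by 0.57 on the log2 scale. Adjusted over the list alone, 7 were lower and 0 higher after quantile normalization. Camera gave adjusted p = 1.3e-08, lost at adjusted p = 0.502 with an estimated correlation. Of 30 genes of fatty acid and triglyceride synthesis, Thrsp, Lpin1 (-1.28 ± 0.23) and Mlxipl, which encodes the glucose-responsive factor ChREBP (-0.64 ± 0.13), fell and Scd2 rose, with 7 lower and 5 higher when adjusted over the list alone (camera adjusted p = 0.064). None of 18 genes of cholesterol synthesis passed in both fits, none when adjusted over the list alone after quantile normalization, and 4 were lower on the deposited values alone. Camera called that list down (adjusted p = 0.022), lost at adjusted p = 0.964 with an estimated correlation.

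Of 22 genes of glucose and glycogen metabolism 6 fell and none rose. They were the glycogen-targeting phosphatase subunits Ppp1r3g (-1.90 ± 0.30) and Ppp1r3b (-0.65 ± 0.14), liver pyruvate kinase Pklr (-0.97 ± 0.12), liver glycogen synthase Gys2 (-0.73 ± 0.15), Pfkfb3 (-0.77 ± 0.18) and the glucose transporter Slc2a2 (-0.55 ± 0.09). With p-values adjusted over the list alone, 9 were lower and 2 higher after quantile normalization. Camera called the list down (adjusted p = 0.00035), lost at adjusted p = 0.681 with an estimated correlation. Of 18 circadian clock genes the repressors Ciart (-1.07 ± 0.24) and Cry2 (-0.85 ± 0.20) fell, with 6 lower and 2 higher when adjusted over the list alone. Camera gave adjusted p = 6.7e-05 for this list, lost at adjusted p = 0.502 with an estimated correlation.

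Of 21 hepatocyte transcription factors, the xenobiotic receptors Nr1i3 (-1.52 ± 0.34) and Nr1i2 (-0.63 ± 0.13) and Ppara fell, and Onecut1 had a difference of 2.26 ± 0.58 (adjusted p = 0.068), with 3 higher and 3 lower when adjusted over the list alone after quantile normalization. Of 30 plasma protein genes coagulation factor F7 alone fell (-0.78 ± 0.11), with 5 lower and 3 higher when adjusted over the list alone. Of 19 cytochrome P450 and conjugation enzymes the carboxylesterases Ces1d (-1.17 ± 0.18) and Ces2a (-0.73 ± 0.14) fell and Cyp2c55 rose (1.81 ± 0.16). Of 18 acute phase genes Lcn2 (1.98 ± 0.21) and Saa3 (1.27 ± 0.14) rose. None of 23 genes of the urea cycle and amino acid catabolism passed in both fits. After quantile normalization and adjusted over the list alone, 9 P450 and conjugation genes, 6 acute phase genes and 4 urea cycle and amino acid genes passed in either direction.

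Single genes moved in other stress and signalling lists. Of 18 apoptosis regulators Casp12 rose (1.98 ± 0.20), of 21 insulin and growth hormone signalling genes the STAT5 target Cish rose (2.22 ± 0.46), and of 7 erythroid genes the transferrin receptor Tfrc rose (1.91 ± 0.20). Of 32 genes of the unfolded protein and integrated stress responses asparagine synthetase Asns rose (2.37 ± 0.55) and Sel1l fell (-0.51 ± 0.10). Of 23 immediate early and dissociation stress genes Myc (1.76 ± 0.24) and Ier3 (1.33 ± 0.18) rose and Fos fell (-1.35 ± 0.27). Of 35 genes of oxidative phosphorylation Cox5b fell (-0.73 ± 0.17). No member of the lists for heat shock proteins (13 genes), ribosomal proteins (24) or autophagy and lysosome (22) passed both fits. Camera called none of these 9 lists on the deposited values.

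The RNA-processing lists held 1 gene past both fits. Neither the 11 SR proteins, the 24 hnRNP proteins nor the 15 genes of nonsense-mediated decay had a member past both fits, and of 46 spliceosome and other splicing factors the CELF family member Celf2 fell (-1.12 ± 0.14). On the deposited values, where most calls were lower, 4 SR genes (Srsf1 among them), 2 hnRNP genes and 5 spliceosome genes were lower. No nonsense-mediated decay gene was called there, and no gene of these lists was higher. Srsf5 had a difference of -0.78 ± 0.23 (adjusted p = 0.110) and Hnrnph3 of -0.82 ± 0.22 (adjusted p = 0.087). The medians of the SR and hnRNP lists were -0.01 and 0.01. Adjusted over the list alone after quantile normalization, 0 SR genes, 3 hnRNP genes and 4 spliceosome genes passed in either direction. Without knockout replicate 1, 3 SR genes were higher and 3 lower after quantile normalization, 5 hnRNP genes were higher and 2 lower, 11 spliceosome genes were higher and 3 lower, and 3 nonsense-mediated decay genes were higher and 0 lower.

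Markers of other liver cells were checked beside these groups. Of 19 macrophage and Kupffer cell markers Gpnmb (3.03 ± 0.28), the lysosomal protein Cd68 (1.81 ± 0.35) and the MHC class II chaperone Cd74 (1.66 ± 0.31) rose, with 10 higher and 0 lower when adjusted over the list alone after quantile normalization. Camera gave adjusted p = 1.55e-14, lost at adjusted p = 0.489 with an estimated correlation. None of 26 stellate cell, fibroblast and matrix genes passed both fits, with 8 higher and 0 lower when adjusted over the list alone (camera adjusted p = 5.65e-07, lost at adjusted p = 0.502 with an estimated correlation), and Vim had a difference of 1.18 ± 0.18 after quantile normalization. Without knockout replicate 1, 12 matrix genes and 10 macrophage genes were higher after quantile normalization, against 1 and 4 with it, and none was lower. No member of the lists for endothelial cells (19 genes), lymphocytes (12), neutrophils (10) or cholangiocytes and progenitors (10) passed both fits. After quantile normalization alone 0, 1, 0 and 1 of these were past the threshold, all higher.

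Genes known to differ between male and female livers were checked as well. Of 15 female-biased genes Sult3a1, Acot3 and the steroid hydroxylase Cyp17a1 (-1.14 ± 0.21) fell and none rose. Of 11 male-biased genes Elovl3, Cyp7b1 and Susd4 (-1.17 ± 0.24) fell and C6 rose. These calls stand beside the male array in the knockout group; without it the differences were -4.40 ± 0.12 for Sult3a1, -2.92 ± 0.18 for Elovl3 and 3.87 ± 0.35 for C6. Adjusted over the list alone after quantile normalization, 5 female-biased genes were lower, 4 male-biased genes were lower and 3 male-biased genes were higher. Camera called the female-biased list down on the deposited values (adjusted p = 3.4e-13), lost at adjusted p = 0.264 with an estimated correlation. After quantile normalization camera gave adjusted p = 0.0006 with the preset and 0.329 with an estimated correlation.

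**Figure D3:**
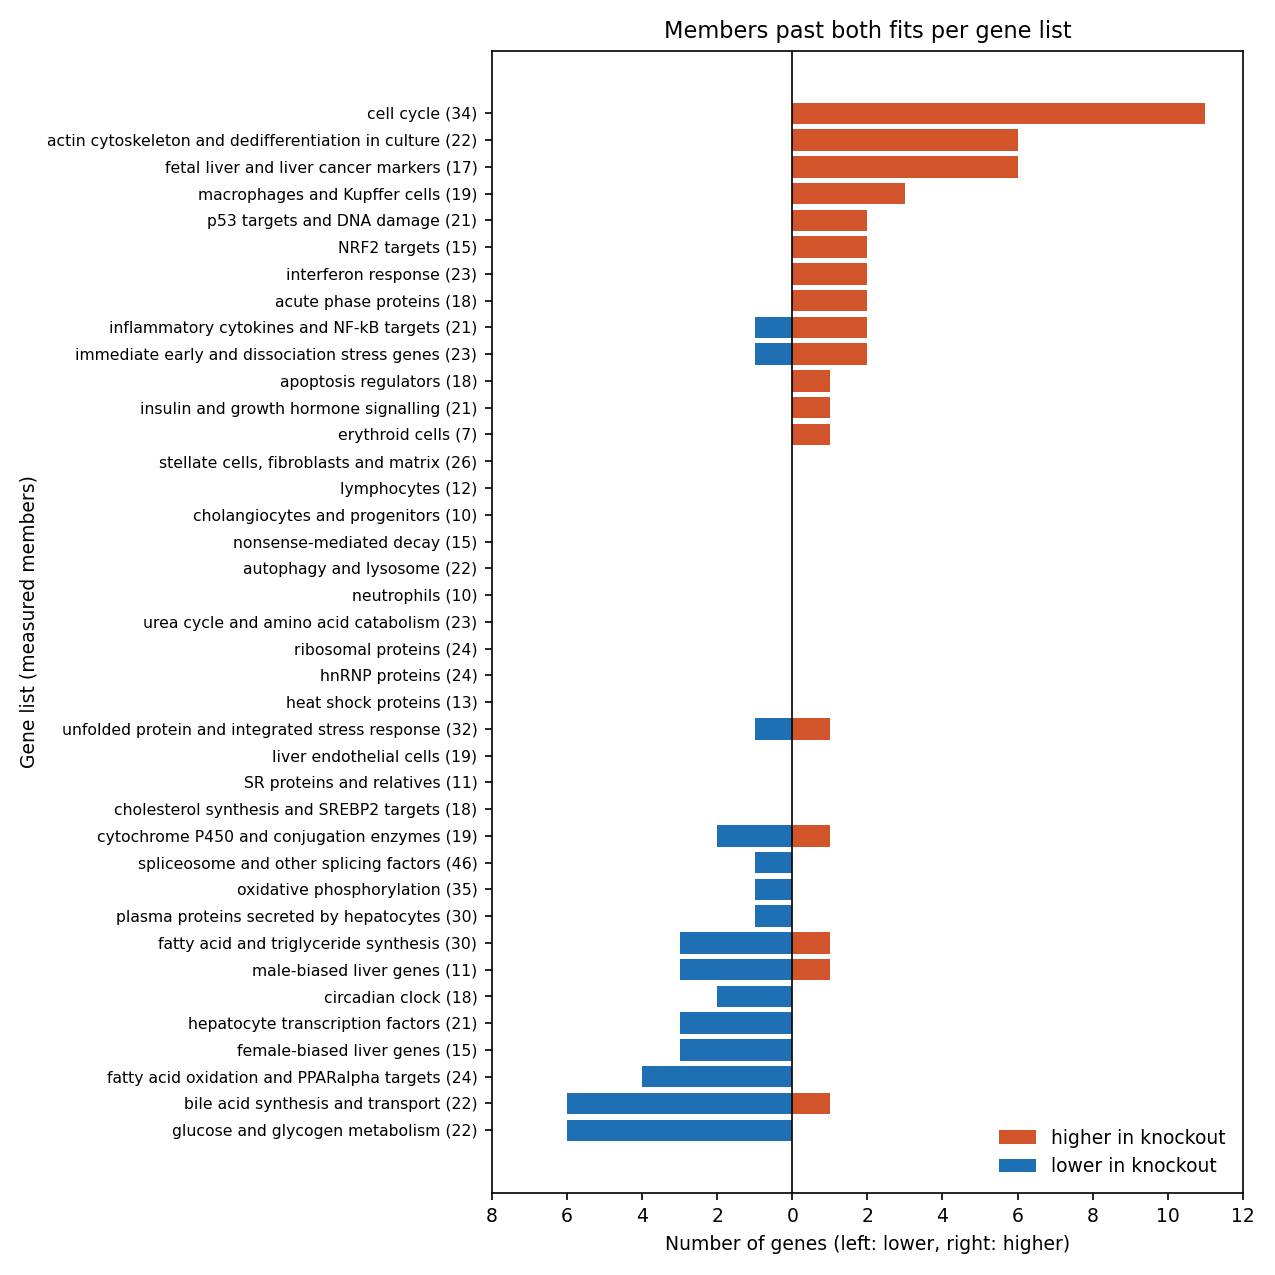
Number of genes of each fixed list that passed limma's test at an adjusted p of 0.05 both on the deposited values and after quantile normalization, with bars to the right for genes higher and bars to the left for genes lower in the knockout (3 against 3 arrays). The number of measured members stands in parentheses; cell cycle genes have the longest bar to the right (11 of 34), and glucose and bile acid genes the longest to the left (6 of 22 each).

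Of the 39 lists tested, camera called 15 on the deposited values, 9 up and 6 down. With an estimated correlation it called 0 (4 at an unadjusted p under 0.05). The rotation test fry, which asks whether the genes of a list move one way on balance, called 0 on the deposited values (12 at an unadjusted p under 0.05), where most genes are lower, and 9 after quantile normalization. Of these 9, 8 were also called by camera: fetal liver markers, NRF2 targets, p53 targets, inflammatory genes, matrix genes, macrophage markers and cytoskeleton genes (up) and glucose metabolism (down). The other was the list of apoptosis regulators (up, fry adjusted p = 0.034). Fry after quantile normalization did not call the cell cycle (adjusted p = 0.071), bile acid (0.088) or fatty acid oxidation (0.062) lists. At the preset correlation camera called 17 lists after quantile normalization, 10 up and 7 down. Those of plasma proteins (down, adjusted p = 0.025) and acute phase proteins (up, adjusted p = 0.044) were not called on the deposited values. With an estimated correlation camera called 0 lists after quantile normalization too (lowest adjusted p = 0.240).

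In no list did fewer genes pass after quantile normalization without knockout replicate 1 than with all 6 arrays. Over all 19123 genes the count went from 792 to 2895 in the same step, so a gain in a list is not by itself a result about that list. Cell cycle genes went from 14 to 22 higher with 0 lower, p53 targets from 2 to 9 higher and from 0 to 2 lower, and interferon genes from 4 to 9 higher and from 0 to 1 lower. NRF2 targets went from 3 to 7 higher with 0 lower, and cytoskeletal genes from 12 to 15 higher and from 0 to 1 lower. Fetal liver markers stayed at 7 higher and went from 0 to 1 lower. Among metabolic lists, fatty acid oxidation went from 4 to 9 lower with 0 higher, glucose genes from 6 to 8 lower with 1 higher, and bile acid genes from 7 to 9 lower and from 2 to 3 higher. Fatty acid synthesis went from 3 to 8 lower and from 2 to 4 higher, and clock genes from 2 to 8 lower with 1 higher. Other lists gained in both directions: hepatocyte transcription factors had 6 higher and 5 lower against 0 and 3 with all arrays, the unfolded protein and integrated stress responses 6 and 7 against 3 and 1, immediate early genes 6 and 7 against 2 and 1, insulin and growth hormone signalling 4 and 6 against 1 and 0, and acute phase genes 5 and 4 against 2 and 0. Female-biased genes had 1 higher and 5 lower against 0 and 3.

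Without joining clusters into genes, 3628 of 143165 transcript clusters passed on the deposited values, 239 higher and 3389 lower (93.4% lower), most of them unnamed here. After quantile normalization 429 passed, 281 higher and 148 lower (34.5% lower). The count on the deposited values was 617 without wild type replicate 1, 1241 without wild type replicate 2 and 6330 without wild type replicate 3, and 18836, 1823 and 1135 without knockout replicates 1, 2 and 3.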

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

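The tests without knockout replicate 1 after quantile normalization and the count past both fits were chosen after seeing the data. No paired analysis was possible because the labels give the groups no shared replicate numbers. The exon usage test and its alternatives were not run, since the table has 1 row per transcript cluster. The array weights did not converge, and their counts are given only as values. With 3 arrays per group the counts moved with the scaling and with single arrays, and the cause was not tested beyond the simulated offsets. Signal near background limits genes of low intensity, whose differences the pseudocount shrinks.

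Against 1489 genes on the deposited values, quantile normalization gave 792 (522 higher, 270 lower), median centring 550 (340 higher, 210 lower), array weights 17435, a log2 difference of at least 1 gave 633 (fewer genes by construction), and quantile normalization without knockout replicate 1 gave 2895. Leaving out 1 array gave 391 to 7104. Against 3628 transcript clusters, these gave 429 (quantile), 340 (median centring, 182 higher and 158 lower), 1127 (no filter), 116063 (array weights), 1685 (quantile, without knockout replicate 1) and 617 to 18836 (1 array left out). Against 428 genes past both fits, the count over all genes tested became 1861 with array weights and 166 to 1198 with 1 array left out, and 375 to 453 under the other alternatives. The direction was less stable than the total: the 453 with median centring were 308 higher and 145 lower, against 161 higher and 267 lower in the main setting. The 15 lists became 0 with an estimated correlation and 0 with fry, and 13 to 22 under the others. Lists called down went from 6 to 13 without knockout replicate 2, 11 without knockout replicate 3 and 3 with median centring. Lists called up went from 9 to 9, 11 and 10 in these settings. The sign turned with fry, which tests against 0, for the lists of p53 targets (median -0.10, adjusted p = 0.991), interferon response (-0.14, 0.927), inflammatory genes (-0.11, 0.781) and matrix genes (-0.045, 0.991) on the deposited values, where the median gene is at -0.44; none of these was past the threshold.

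The Srsf1 difference of -0.95 stayed negative throughout but was not past the threshold after quantile normalization (-0.53), median centring (-0.63), with the median of its clusters (-0.63), after quantile normalization without knockout replicate 1 (-0.35), or when any 1 array except wild type replicate 3 was left out (-1.07 to -0.75). Its adjusted p ran from 1.2e-23 with array weights to 0.346 with median centring. Of the 24 named genes, all kept their direction, and 21 or more stayed past the threshold under each alternative that refits the model. The calls lost were those of Xist, Ces3b and Npr2 with quantile normalization, Xist with median centring, without wild type replicate 3, and without knockout replicate 1 after quantile normalization, and Rgs16, Xist and Ces3b with robust variances.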

Other observations

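Apart from the counts of other splits, the tests in this part were chosen after the results they bear on had been seen. The tests of the ChREBP targets, the imprinted and the macrophage genes, with the intensity limit of the latter, were also revised after earlier forms of them had been run. Genes named here that no list holds were likewise chosen after their values were seen.

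Several genes that respond to glucose through the factor ChREBP were lower in the knockout. Txnip, its relative Arrdc4 (-1.17 ± 0.19), Thrsp, Rgs16, Klf10 (-1.36 ± 0.25), Pklr, Slc2a2 and Mlxipl, which encodes ChREBP, all passed both fits. A list of 16 further measured targets, among them Fasn, Acly and Khk, was set against 10000 random lists of matched mean level. Their median difference was -0.18, at percentile 4.16 of the random lists, which leave correlation between genes aside. Of the 16, 12 were below 0 and none passed both fits. The 8 genes named above, all past both fits, had been taken out of this list. The choice therefore largely set that none of the rest passed. Over all 24 the median was -0.33, a value that includes the 8 noticed genes. Camera with an estimated correlation gave p = 0.0707 and fry p = 0.026 after quantile normalization, neither adjusted for the 2 lists tried, so a shared fall of ChREBP targets is left open.

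H19, Igf2 and Phlda2 lie in neighbouring imprinted domains and rose. Of 29 other measured imprinted genes, 1 passed as higher (Sgce, 1.46 ± 0.32) and none as lower. Over all 32, these 3 included, the median was 0.026 with an interquartile range of 0.46, and over the 29 others it was 0.015. The smallest of the 3 differences was 1.79 (Igf2). The 3 were noticed for their rises, so their lying above the median was set by choice. The medians themselves, over genes called or not, argue against a like rise of imprinted genes in general. A one-sided Fisher exact test of the count among the 29 against all genes tested gave p = 0.218. That test left out the 3 noticed genes and does not cover them. A change limited to those domains was not tested.

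Most calls on the deposited values were lower in the knockout. If array scaling was the cause, clusters too dim to report expression should shift as well, and they did: clusters under the filter had a median difference of -0.43 on a log2(intensity + 1) scale, against -0.51 for the named genes. Of the 10 splits of the 6 arrays into groups of 3, another split gave 2084 genes against 1489 for the real one; it set wild type replicates 1 and 2 with knockout replicate 1, the 3 arrays of highest median intensity, against the rest, which points to a structure of the samples in brightness. No biological explanation was tested for this pattern. The arrays measured isolated total RNA, so these values cannot show whether the RNA per cell changed.

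Of 15 female-biased genes 3 fell, while 1 of the knockout arrays came from a male. Without that array, Sult3a1, Acot3 and Cyp17a1 stayed below 0 by more than 2 standard errors, with Cyp17a1 closest to 0 at -0.90 ± 0.15. These 3 were thus also lower among female arrays. Genes low in the male array alone tend to fail the quantile-normalized fit through their spread. All 428 genes past both fits also passed after quantile normalization without that array. The choice of these 3 therefore largely set this outcome, and it does not bear on the rest of the list. For Xist, which did not pass both fits, leaving out that array left -0.15 ± 0.14, as a male array would give. Whether the sexes respond differently to the loss of SRSF1 cannot be tested with 1 male array.

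Gpnmb, Cd68 and Cd74 rose, as did Cybb, a phagocyte gene outside the list, and a larger share of macrophages could raise them. More cells of the usual makeup would raise the brightest markers alike. The 7 list members of wild type intensity of at least 100, Cd74 included, had a median difference of 0.73 with an interquartile range of 0.36, below the smallest of the 3 differences at 1.66; Mpeg1 had 0.97 ± 0.25, C1qb 0.76 ± 0.26 and Clec4f 0.13 ± 0.13. The 3 genes were the list members past both fits, so they lie above the list median by choice. This comparison therefore cannot decide the source of their increases. As all 7 bright members and 18 of all 19 members were above 0, a rise in macrophages stays open, as do a different macrophage state and expression in hepatocytes.

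In the other 9 of the 10 splits of the arrays, 0 genes passed after quantile normalization or in both fits, against 792 and 428 in the real split. Thus 1 split of 10, the real one, gave as many. Each of the other 9 mixes wild type and knockout arrays, so any difference between the real groups adds to the spread within the mixed ones. Their counts therefore do not show what arrays without such a difference would give. For transcript clusters on the deposited values the highest of the others was 38 against 3628, and the real split was again the 1 that gave as many. For the lists called by camera, 9 of 10 splits gave as many as the 15 of the real one and the highest other gave 26, so camera with the preset correlation of 0.01 called lists in most groupings of these arrays. On the deposited genes 2 of 10 splits gave as many as the real one. With 10 splits no share under 0.05 can be reached in any of these.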
